A study of Nostoc punctiforme with 2 samples.

How the data were processed

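RNA of Nostoc punctiforme zwf and zwf sigG strains was compared on 6 slides of a 2-colour spotted array, 3 for vegetative growth and 3 for cultures darkened for 48 hours. Per the labels' protocols, cultures of 50 ml grew at 25 degrees with ammonia, nitrate and fructose, 15 micrograms of total RNA were made into cDNA, and the cDNA was labelled with 1 of 2 Alexa dyes. Per the labels and the deposited slides' own descriptions, each condition had 2 biological replicates, and replicate 2 was hybridised on 2 slides with the dyes exchanged. These 2 slides hold the same extracts and were averaged to 1 value, so n = 2 per condition, and whether the replicates came from separately started cultures is not given in the sources used here. Which strain was in which channel was read from the marks for experiment and control in the deposited slides' own names together with the labels' naming of the strains.

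Per the file headers, the slides were scanned on a GenePix scanner 4000B and quantified with GenePix Pro 6.0, with a local background for each spot and no normalization. The intensity values used were the median pixel brightness of spot and background and the SD of the background pixels at 635 and 532 nm, per the file headers. The percent of saturated pixels of each spot was used as deposited by the authors. Other deposited values used were the scanner's codes for bad or missing spots, per the file headers. The authors' deposited table of log2 ratios, whose making is not given in the sources used here, was used as an alternative. Its columns had medians of -0.00115 and 0.00295, and correlated with the ratios computed here at r = 0.916 and 0.956 across 2517 matched genes. The slopes, taken only among values over 0.4, were 0.919 and 0.837. For these values its scale is that of log2 ratios and its direction the same, while its centring and replicate handling stay unknown. In the authors' deposited table, sigG had -4.08 and -4.83, and 16 genes were at 1 or more and 13 at -1 or less in vegetative growth, and 11 and 23 after induction.

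Background was corrected with limma's normexp (offset 50), the log2 ratio of each slide was normalized by loess, with control spots given no weight, and every ratio was turned to zwf sigG over zwf. Of 15552 spots per slide, 13794 carried genes, and between 10 and 181 gene spots per slide were left out because the scanner marked them as bad. The 2 spots of a gene (4 for 5 genes) were averaged. A gene was tested if it was brighter than the background by 2 background SDs in either channel on at least 2 slides of at least 1 condition, which kept 2522 of 6892 genes and left 4370 untested. Between 2 and 6 gene spots per slide were saturated. Names are those of the array's annotation, which is old, and 6552 locus tags matched a RefSeq gene table of assembly ASM2002v1, used only for names and neighbours, of which 899 had a symbol, while 340 did not match. The symbol sigG is in neither, and Npun_F4153 was taken as sigG because the scanner headers carry its locus number and the array annotates it as a sigma factor.

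Strain effects were tested with limma (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05, two-sided) on the 4 replicate values, with both conditions sharing the estimate of the spread (2 residual and 4.12 prior degrees of freedom). SE are those of this fit. For a named gene at background in 1 channel on every slide of a condition, a bound is given beside the ratio, from the mean of its bright channel against the higher of its own dim signal and the lowest signal above background on each slide, after Aquantile scaling of separate channels, which is open to dye bias because replicate 1 had no exchanged slide. The shift of the zwf strain used the separate channels in limma. Gene lists (27, fixed with the designs, alternatives and naming rule before the data were examined) were tested with camera at a preset correlation of 0.01, 81 tests in 1 family, and with fry and an estimated correlation as alternatives, by which 0 of these 81 tests passed. In the zwf shift, 1 of 27 lists passed camera, 0 with an estimated correlation and 11 by fry. They were matched by symbol and product words, so single members can be foreign to a list, such as a macrophage migration inhibitory factor among phage genes. A count by size took genes with a mean log2 ratio of 1 or more and the same sign on all 3 slides. R 4.3.3, limma 3.58.1, data.table version 1.17.8, jsonlite 2.0.0 and statmod 1.5.0 were used.

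Genes were named by rule: sigG, zwf, the 2 tested genes on each side of sigG and sigma factors past the threshold, then per condition up to 12 genes in each direction past the threshold with the same sign on all slides, filled by unadjusted p with genes of at least 2-fold ratio and the same signs, with at most 3 of unknown function in each direction. The difference took 6 in each direction in the same way, and each list described its 2 to 4 members with the smallest p. The genes with the largest shift in the zwf strain, the nitrate genes and the further neighbours of the phage tail sheath genes were chosen after their values were seen.

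The fit was tested on simulated slides of 2522 genes, and the simulation was corrected once, after its first version had placed the strain effect in both channels and so called unchanged genes in the zwf shift. For vegetative growth, 73.1% of genes changed 2-fold, 100% changed 4-fold and 98.5% changed 16-fold were called, with 0.431% of unchanged genes. For the induced condition the shares were 71.6%, 100%, 100% and 0.474%. For the zwf shift they were 100% at each fold, with 0.904%. The simulated noise of the zwf channel between slides was a set value, not one fitted to the data. The shares for the zwf shift therefore do not show how well real shifts are found. The simulated slides held no scan day effect, so these shares say nothing about one. In each condition 67, 67 and 66 genes were changed 2-fold, 4-fold and 16-fold, with independent noise of the fitted spread in the strain ratios. So many changed genes make the adjusted threshold easier to pass than with the few calls in the data. Genes left uncalled in the data can therefore still have changed. The number of arrays limits the precision of all values. Alternatives tried were other background corrections, median centring, print-tip loess, scaling between slides, no brightness filter, other spot summaries, dye terms, 6 slides as separate values, each condition alone, another variance model, a replicate block, leaving out each replicate or slide, the authors' table and, chosen later, scan day terms. Replicate numbers are shared by the conditions, but no source says that a number marks a shared batch, so no pairing was assumed.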

Results

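Nostoc punctiforme is a filamentous cyanobacterium whose vegetative cells can differentiate into akinetes, spore-like resting cells. RNA of a strain labelled as a zwf mutant was compared on 2-colour arrays with RNA of a zwf sigG double mutant, which also lacks a sigma factor of RNA polymerase. The name zwf stands for glucose-6-phosphate dehydrogenase of the oxidative pentose phosphate pathway. The labels do not say which of 3 loci with this name is mutated. The strains were compared in exponential vegetative growth and after 48 hours of darkness, the akinete-inducing treatment, in medium with ammonia, nitrate and fructose. Each condition had 2 biological replicates on 3 slides, because replicate 2 was hybridised again with the dyes exchanged. Slides 1 to 3 were vegetative and slides 4 to 6 akinete-induced, with replicate 1 on slides 1 and 4. Slides 1, 2 and 5 had the same dye orientation, and slides 3, 4 and 6 had the other. Replicate 1 had no exchanged slide, so gene-specific dye bias is not cancelled in it. Any such bias enters the 2 conditions with opposite sign. The slides carried spots of 6892 genes, and between 22.9% and 33.8% of these were above background on a slide, so 2522 genes were tested. All ratios below are zwf sigG over zwf, on the log2 scale, as mean ± SE with n = 2.

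The first question was whether the deleted gene was low on every slide. The locus Npun_F4153, annotated as an RpoE-type sigma factor, is taken here as sigG, because the scanner headers of 6 slides carry its locus number. Its ratio was -4.54, -4.45 and -5.07 on the vegetative slides and -4.46, -6.12 and -5.13 on the akinete-induced slides. In the zwf sigG channel it was not above background in either condition, so transcript was at least 11.7-fold lower in vegetative growth and at least 16.7-fold lower after induction. Of the tested neighbours, Npun_F4154, a possible anti-sigma factor at the next locus, had ratios of -0.53 ± 0.20 and -0.80 ± 0.20, and Npun_R4155 had -0.48 ± 0.26 (at least 1.12-fold lower, as its zwf sigG channel was at background) and -0.86 ± 0.26. On the other side, Npun_F4149 (NlpD) had 0.16 ± 0.19 and -0.11 ± 0.19, and Npun_F4150 had 0.31 ± 0.23 and 0.06 ± 0.23. None of these neighbours passed the threshold in either condition. Npun_F4025, annotated as zwf, was above background in both strains and both conditions, with ratios of -0.23 ± 0.18 and -0.09 ± 0.18, and the other 2 loci with that name, Npun_F2978 and Npun_F3304, were not tested because they were too dim.

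**Figure D1:**
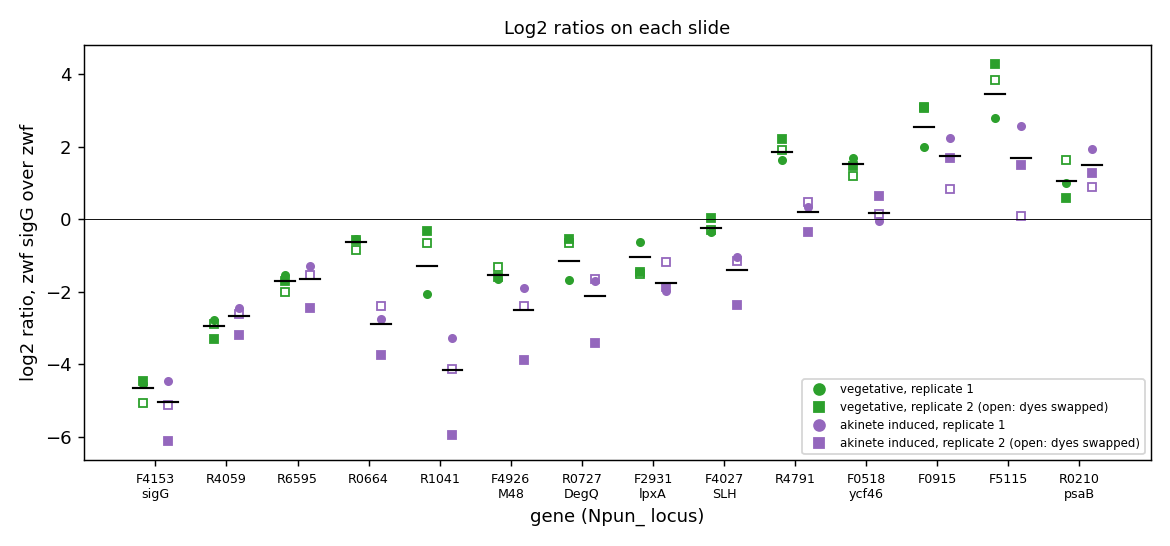
Log2 ratios (zwf sigG over zwf, vertical axis) of 14 genes on each of the 6 slides, with circles for replicate 1, squares for replicate 2, open squares for exchanged dyes and bars for the mean of the replicates. Npun_F4153 lay between -6.12 and -4.45 on all slides, and Npun_R0664 was below -2 only on the akinete-induced slides, while on the vegetative slides both its channels were at background.

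In vegetative growth, transcripts of 2 genes fell in the zwf sigG strain and none rose. sigG (Npun_F4153) fell by 4.65, a bound of at least 11.7-fold (adjusted p = 0.009). Npun_R4059, a conserved protein of unknown function, had a ratio of -2.94 ± 0.21, which is 7.68-fold lower, and was lower on all 3 slides (adjusted p = 0.009). The genes named next did not pass the threshold. They were taken by p among genes of at least 2-fold mean ratio and the same sign on all 3 slides. Their shared sign therefore follows from the choice and is no added evidence. Among those with positive ratios, Npun_R4791, a precorrin reductase of cobalamin synthesis, had 1.84 ± 0.21 (adjusted p = 0.084), and Npun_F6483 (cobI), a precorrin methyltransferase of the same pathway, had 1.28 ± 0.26. The neighbours Npun_F0517 and Npun_F0518 (ycf46), the latter an ATPase, had 1.67 ± 0.21 and 1.51 ± 0.21. Npun_F0915, with a TROVE RNA-binding domain, had 2.53 ± 0.35, and Npun_F5115, of unknown function, had 3.44 ± 0.48. Positive ratios were also measured for Npun_R2778, an HNH endonuclease, with 1.98 ± 0.50, its near neighbour Npun_R2775 with 1.58 ± 0.26 (at least 1.29-fold higher, with the zwf channel at background), psaB (Npun_R0210) of photosystem I with 1.06 ± 0.25 and the plasmid-borne VirB4 gene Npun_AR048 with 1.01 ± 0.19. The 2 replicates lay apart for Npun_F5115 (2.8 and 4.07), Npun_R2778 (1.06 and 2.9) and Npun_F6483 (0.83 and 1.73).

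Among genes with negative ratios in vegetative growth, Npun_R6595, of unknown function, had -1.69 ± 0.24 (adjusted p = 0.11), and the membrane peptidase Npun_F4926 (family M48) had -1.55 ± 0.31, a bound of at least 2.06-fold. Neighbours around 2 genes annotated as phage tail sheath proteins had negative ratios too, with the sheath genes Npun_F1402 and Npun_F1403 at -1.50 ± 0.32 and -1.22 ± 0.18. Of the hypothetical genes beside them, Npun_F1401 was at -1.74 ± 0.30, Npun_F1404 at -1.45 ± 0.23 and Npun_F1406 at -1.48 ± 0.32, a bound of at least 2.1-fold. On slide 2, of replicate 2, Npun_F1401, Npun_F1402 and Npun_F1406 were at background in both channels. Replicate 1 had the lower ratios, with -2.33 against -1.16 for Npun_F1401, -2.16 against -0.83 for Npun_F1402 and -2.11 against -0.852 for Npun_F1406. Npun_R0421, a possible sugar dehydrogenase, had -1.12 ± 0.20. By size, 32 genes differed by at least 2-fold with the same sign on all 3 slides, 15 higher and 17 lower, against 0 when the sign of replicate 1 was turned. Without replicate 1 the number was 64 (31 higher, 33 lower), and without replicate 2 it was 47 (18 higher, 29 lower). The 47 rest on slide 1 alone, where any gene meets the same-sign condition.

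**Figure D2:**
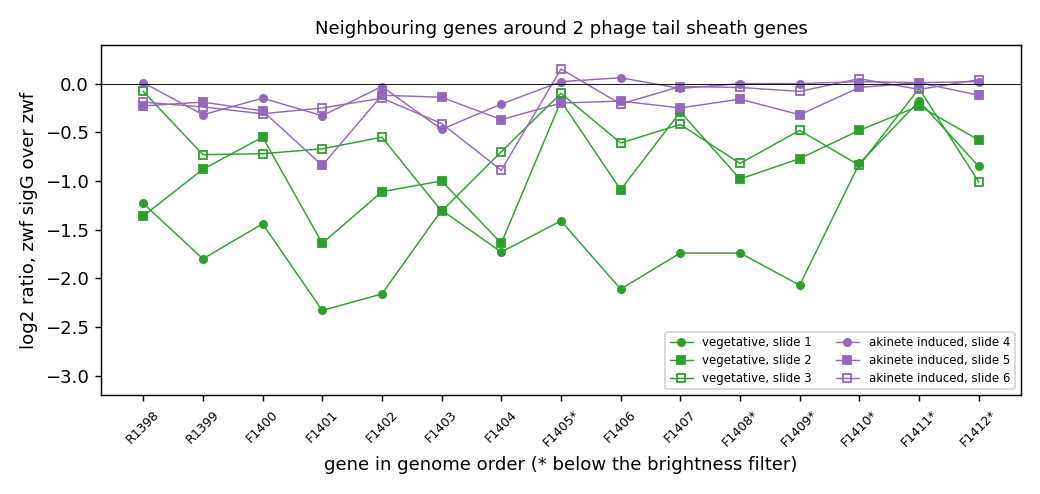
Log2 ratios (zwf sigG over zwf, vertical axis) of the phage tail sheath genes Npun_F1402 and Npun_F1403 and their neighbours in genome order, 1 line per slide, vegetative in green and akinete-induced in purple, with an asterisk on genes below the brightness filter. The mean of the 9 tested genes from Npun_R1398 to Npun_F1407 was -1.76, -1.06 and -0.64 on the vegetative slides and -0.17, -0.29 and -0.30 on the others, where most of these genes were at background in both channels. On vegetative slide 2, Npun_R1398, Npun_F1401, Npun_F1402, Npun_F1406 and Npun_F1407 were at background in both channels as well.

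Of the 27 gene lists, 2 lay lower than other genes in vegetative growth by limma's camera with a preset correlation. Of 53 tested genes of the ribosomal protein list, 43 had negative ratios, with a mean of -0.172 (adjusted p = 0.036), and none passed limma singly, either over all genes or adjusted over the list alone (3 did at an unadjusted p under 0.05). Examples were rplF (Npun_R4376) with -0.77 ± 0.20, rpsQ (Npun_R4381) with -0.51 ± 0.19 and RimK (Npun_F2190), a modification enzyme, with -0.57 ± 0.19. Of 25 phycobilisome genes, which encode the light-harvesting antenna, 21 had negative ratios, with a mean of -0.215 (adjusted p = 0.047), and again none passed singly, over all genes or adjusted over the list alone (1 did at an unadjusted p under 0.05). Examples were the linkers cpcC (Npun_F5292) with -0.51 ± 0.20 and cpeE (Npun_F0736) with -0.48 ± 0.20. Both calls were lost with an estimated correlation (adjusted p = 0.91 for each), with median centring (adjusted p = 0.078 and 0.059), without vegetative replicate 2 (means of -0.096 and -0.105, adjusted p = 0.53 and 0.63) and without akinete-induced replicate 1 (adjusted p = 0.064 for each) or 2 (adjusted p = 0.061 for each). Without vegetative replicate 1 the means were -0.248 and -0.325 (adjusted p = 0.041 and 0.042). With the scan day as a term they were -0.172 and -0.215 (adjusted p = 0.042 and 0.04). Each scan day held 1 vegetative replicate, so that term cannot move the vegetative means and is no separate check of them. Within scan day 1 they were -0.248 and -0.325, the values of vegetative replicate 2 alone. The sigma factor list had 1 call adjusted over the list alone, sigG itself, and the list of transposases and phage genes had 3.

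The vegetative calls rested on limma with 2 residual degrees of freedom. At an unadjusted p under 0.05, 158 genes passed (53 higher, 105 lower), where 126 would be met by chance. A planned limma fit of the 6 slides with a dye term called 41 genes (19 higher, 22 lower), among them Npun_R4791, Npun_F0517, Npun_F0518, Npun_F0915, Npun_F5115, Npun_F6483, Npun_R6595, Npun_F1401, Npun_F1403, Npun_F1404 and Npun_R0421. That fit estimated a correlation of -0.119 within replicates, so slides of the same extracts were not discounted as repeats. Scaling moved the split, with 11 higher and 13 lower after median centring, 4 and 5 after print-tip loess and 4 and 2 with no offset. The slides were scanned on 2 days, and the calls for sigG and Npun_R4059 were lost with a scan day term on the 4 replicate values (-4.65 and -2.94, adjusted p = 0.26 for each) and within scan day 1 (-4.76 and -3.09, adjusted p = 0.15 for each), while a fit of the 6 slides as independent values with scan day and dye terms called 3 genes. They were lost as well without vegetative replicate 1 or 2 (adjusted p = 0.4 and 0.29 for each), with scaling between slides (adjusted p = 1 for each) and without the brightness filter (adjusted p = 0.34 for each), and that of Npun_R4059 with a trended robust variance model (adjusted p = 0.094). Scan day 2 held 1 vegetative slide, on which their ratios were -4.54 and -2.79. That slide is replicate 1, so in vegetative growth scan day and replicate cannot be told apart. A scan day term on the 4 replicate values therefore cannot move the vegetative ratios.

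After 48 hours of darkness, transcripts of 3 genes fell in the zwf sigG strain and none rose. sigG (Npun_F4153) fell by 5.04 (adjusted p = 0.0058), with its zwf sigG channel at background, so the bound given above applies. Npun_R0664, a conserved protein of unknown function, had a ratio of -2.90 ± 0.19, which is 7.48-fold lower, on all 3 slides (adjusted p = 0.0058), and Npun_R4059 had -2.67 ± 0.21, which is 6.37-fold lower, also on all 3 slides (adjusted p = 0.011). sigG and Npun_R4059 were thus past the threshold in both conditions. Npun_R1041, of unknown function, had -4.16 ± 0.51 and was not above background in the zwf sigG channel, at least 13.9-fold lower, but did not pass the threshold (adjusted p = 0.082; -3.28 and -5.03 in replicates 1 and 2). Npun_F4926, the M48 peptidase, had -2.51 ± 0.31, at least 3.42-fold lower (adjusted p = 0.082; -1.89 and -3.12), and Npun_F0817 had -2.29 ± 0.29, at least 2.37-fold lower (adjusted p = 0.082).

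Further genes with negative ratios after induction did not pass the threshold. The protease DegQ (Npun_R0727) had -2.11 ± 0.33, lpxA (Npun_F2931), the first acyltransferase of lipid A synthesis, had -1.75 ± 0.27, the S-layer domain protein Npun_F4027 had -1.40 ± 0.23, and the protein kinase Npun_F6098 had -1.47 ± 0.21, a bound of at least 1.42-fold. Positive ratios on all 3 slides were measured for Npun_F0915 with 1.75 ± 0.35, Npun_F1207 with 1.72 ± 0.44 (at least 2.71-fold higher, with the zwf channel at background), Npun_F5115 with 1.69 ± 0.48, psaB (Npun_R0210) with 1.5 ± 0.25, trxB (Npun_R0672), a thioredoxin reductase, with 1.18 ± 0.52, the methyltransferase Npun_R0602 with 1.06 ± 0.31 (at least 1.42-fold), Npun_R2775 with 1.06 ± 0.26 (at least 1.25-fold) and Npun_R2778 with 1.03 ± 0.50. Replicate 1 carried several of these, with 2.05 against 0.304 in replicate 2 for trxB, 2.58 against 0.786 for Npun_F5115, 1.71 against 0.343 for Npun_R2778 and 1.48 against 0.632 for Npun_R0602. By size, 34 genes had a mean ratio of at least 2-fold and the same sign on all 3 slides, 9 higher and 25 lower. The number was 29 when the sign of replicate 1 was turned. Of these, 6 higher and 8 lower genes also met the size rule in vegetative growth, on slides that share scan days between the conditions.

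The lists of outer membrane genes and of polysaccharide synthesis lay lower than other genes after induction by camera. The third envelope list, peptidoglycan and cell division, did not (36 genes, 16 with positive and 20 with negative ratios, adjusted p = 0.74). Of 31 tested genes of the outer membrane list, 20 had negative ratios, with a mean of -0.282 (adjusted p = 0.014). None passed limma over all genes (7 lower did at an unadjusted p under 0.05), and 4 passed adjusted over the list alone, where the smallest p belonged to lpxA, Npun_F4027, lptB (Npun_R1131), the lipopolysaccharide export ATPase, with -0.89 ± 0.18 (at least 1.43-fold lower), and Npun_F1455, a D15-type surface antigen, with -1.21 ± 0.29 (at least 1.55-fold lower). Of 40 genes of polysaccharide synthesis and glycosyl transfer, 28 had negative ratios, with a mean of -0.211 (adjusted p = 0.0097), none passed over all genes (5 lower did at an unadjusted p under 0.05) and 1 passed adjusted over the list alone. Its members with the smallest p were the glycosyl transferases RfaG (Npun_F3483) with -1.49 ± 0.25, WcaA (Npun_R0658) with -0.82 ± 0.20 and Npun_F5566 with -1.19 ± 0.32 (at least 1.29-fold lower). Both calls were lost with an estimated correlation (adjusted p = 0.91 for each) and without akinete-induced replicate 2 (adjusted p = 0.061 and 0.17), the outer membrane call also without vegetative replicate 2 (adjusted p = 0.051), and the polysaccharide call also without akinete-induced replicate 1 (adjusted p = 0.064), with a dye term (adjusted p = 0.11) and without the brightness filter (mean of -0.0603, adjusted p = 0.46). Median centring gave outer membrane and polysaccharide means of -0.165 and -0.124 (adjusted p = 0.012 and 0.024), and without the filter the outer membrane mean was -0.181 (adjusted p = 0.03). With a scan day term the outer membrane and polysaccharide means were -0.302 and -0.191 (adjusted p = 0.053 and 0.099), and within scan day 1 they were -0.208 and -0.199 (adjusted p = 0.39 and 0.028). Adjusted over the list alone, 2 proteases (Npun_F4926 and DegQ) and 2 members of the sigma factor list (sigG and the anti-sigma factor gene Npun_F4154) passed after induction with negative ratios. Of the photosystem I list psaB passed with a positive one, and none of these 3 lists passed camera (adjusted p = 0.77, 0.21 and 0.77).

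At an unadjusted p under 0.05, 90 genes passed after induction in limma (21 higher, 69 lower), where 126 would be met by chance. The planned dye-term fit of the 6 slides, which did not discount repeated extracts, called 22 genes (1 higher, 21 lower). These included Npun_R1041, Npun_F4926, Npun_F0817, DegQ, lpxA, Npun_F4027, Npun_F6098 and RfaG (Npun_F3483) among the lower, and psaB (Npun_R0210) was the 1 higher gene. A second locus named psaB, Npun_F3819, was not called, with 0.33 ± 0.23 in vegetative growth and a difference between conditions of -0.33 ± 0.33. Median centring in place of loess called 59 higher and 24 lower genes. Replicate 1, on 1 slide, stood apart from the others: without it 37 genes met the 2-fold rule (3 higher, 34 lower) and 19 were called (0 higher, 19 lower). Without replicate 2 the split turned, with 175 by the 2-fold rule (126 higher, 49 lower). Only slide 4 was left there, so nothing was averaged and any gene met the same-sign condition. Slide 4 also had the largest SD of log2 ratios (0.598), so the 175 is not like the other counts. The calls for sigG, Npun_R4059 and Npun_R0664 were lost with a scan day term on the 4 values (-5.12, -2.66 and -2.90, adjusted p = 0.36 for each) and within scan day 1 (-4.8, -2.53 and -2.56, adjusted p = 0.056, 0.071 and 0.071), while the fit of the 6 slides with scan day and dye terms called 22 genes. They were lost as well without vegetative replicate 1 or 2 or with the condition fitted alone (adjusted p = 0.073, 0.083 and 0.073), with scaling between slides (adjusted p = 0.29, 0.31 and 0.36) and without the brightness filter (adjusted p = 0.29, 0.29 and 0.20), and that of Npun_R4059 with a trended robust variance model (adjusted p = 0.1). Scan day 2 held 1 akinete-induced slide, on which the ratios were -6.12, -3.19 and -3.74.

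**Figure D3:**
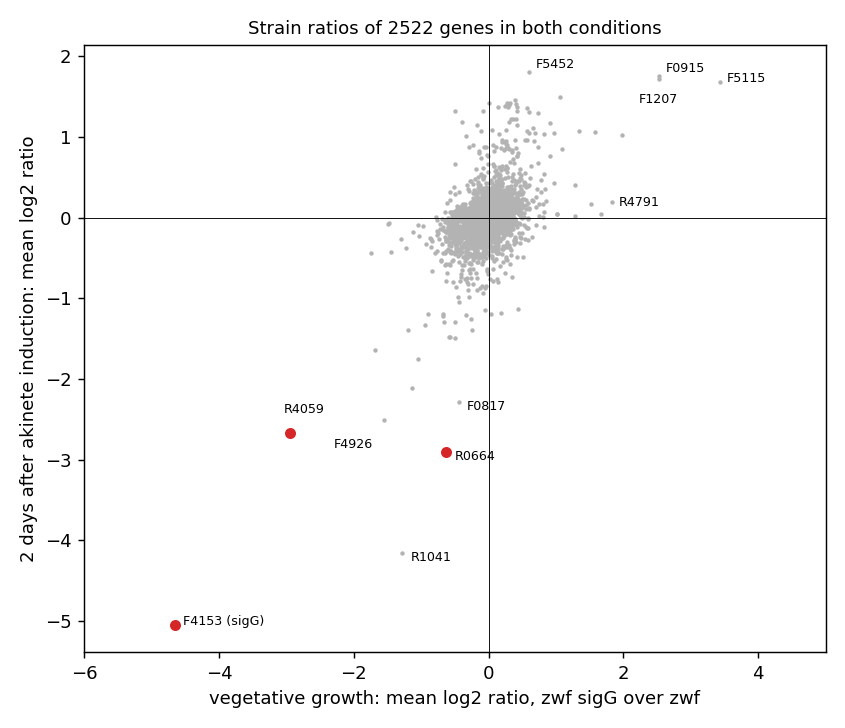
Mean log2 ratio (zwf sigG over zwf) of each of the 2522 tested genes in vegetative growth (horizontal axis) and 2 days after akinete induction (vertical axis), with genes past the threshold in red. Npun_F4153 (sigG) and Npun_R4059 lay far below 0 on both axes, and Npun_R0664 at -0.63, where both its channels were at background, and -2.90.

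The third comparison asked whether the effect of sigG loss differed between the conditions, as the ratio after induction minus that in vegetative growth. Dye bias left in replicate 1 would add up in this difference, because its slides had opposite dye orientations in the 2 conditions. No gene passed limma's threshold for the difference, and none did in the fit of the 6 slides with a dye term. The smallest p belonged to Npun_R0664, with a difference of -2.28 ± 0.27 (unadjusted p = 0.00015, adjusted p = 0.37). In vegetative growth both its channels were at background, so the size of this difference is not measured. Further below the threshold were Npun_R1041 with -2.88 ± 0.72 and Npun_F0817 with -1.85 ± 0.41, and the same limit holds for both. In vegetative growth Npun_F0817 was at background in both channels and Npun_R1041 in the zwf sigG channel. Npun_R4791 had -1.65 ± 0.29, Npun_F0517 had -1.63 ± 0.30 and ycf46 (Npun_F0518) had -1.35 ± 0.30, also short of the threshold. Npun_F6209, a possible multicopper oxidase that was above background in both strains and conditions, had a positive difference of 1.17 ± 0.26. Positive values for Npun_F1406 (1.42 ± 0.45), Npun_F1402 (1.41 ± 0.46), Npun_F1401 (1.31 ± 0.42) and Npun_F1404 (1.03 ± 0.32) do not measure a changed strain effect. After induction Npun_F1401 was at background in the zwf sigG channel and the others in both channels. Npun_F1403 had a difference of 0.85 ± 0.26, short of the threshold (unadjusted p = 0.017, adjusted p = 1). After induction its zwf sigG channel was above background on slide 5 alone and its zwf channel on slides 4 and 5. The size of its difference is therefore limited in part in the same way. At an unadjusted p under 0.05, 48 genes passed (17 higher, 31 lower), where 126 would be met by chance, and without akinete-induced replicate 1 or 2 the number past the adjusted threshold was 4 (0 higher, 4 lower) and 64 (51 higher, 13 lower).

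Of the 27 lists, ribosomal proteins differed between the conditions by camera, with a mean difference of 0.204 over 53 tested genes, 40 of them positive (adjusted p = 0.002). Examples were rpsS (Npun_R4386) with 0.90 ± 0.37 and rplF (Npun_R4376) with 0.74 ± 0.28, and no member passed limma singly, over all genes or adjusted over the list alone (2 did at an unadjusted p under 0.05). The call was lost with an estimated correlation (adjusted p = 0.91) and without vegetative replicate 2 or akinete-induced replicate 2 (mean differences of 0.128 and 0.113, adjusted p = 0.24 and 0.75). Median centring and a dye term gave 0.378 and 0.37 (adjusted p = 4.3e-05 and 9.8e-05). With a scan day term the mean difference was 0.252 (adjusted p = 7.4e-05), and within scan day 1 it was 0.232 (adjusted p = 0.0073). Across the 2522 genes, the mean ratios of both conditions correlated at r = 0.524 and rho = 0.418, where genes are not independent replicates and the conditions share scan days. The replicates within a condition correlated at r = 0.19 in vegetative growth and 0.192 after induction. These are between single replicate values, while the r of 0.524 is between means of 2, so the sizes cannot be compared directly. Slides of the same extracts correlated at 0.534 (slides 2 and 3) and 0.235 (slides 5 and 6). Single slides of different conditions correlated at r = 0.314 to 0.532 on the same scan day and at most 0.188 on different days.

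The last comparison described what darkness did in the zwf parent strain, from its channel on the 3 slides of each condition. It is a comparison between slides and so less direct than the ratios. The zwf channel of replicate 1 also held a different dye in each condition, so dye bias can enter this shift. With a dye term on the 6 slides, 1276 genes passed, but that fit counted slides of the same extracts as separate values. In limma, 674 genes rose and 571 fell, of which 36 rose and 97 fell by at least 4-fold, and the median over all tested genes was 0.0741. Where the zwf channel was at background on every slide of a condition, a bound is given. The largest fall belonged to Npun_F3687 (CynT), named as a carbonic anhydrase, with -5.70 ± 0.23, at least 43.6-fold lower (adjusted p = 3.3e-12). Of the 7 tested genes of carbon fixation and carboxysome, 3 fell, 1 rose and 3 did not pass (list adjusted p = 0.18), with ndhF3 (Npun_F3686) at -4.26 ± 0.24 and chpXY (Npun_F3690), of carbon dioxide hydration, at -2.91 ± 0.23 (at least 5.25-fold lower). Of 6 genes of secondary metabolism, 3 fell and 3 did not pass (list adjusted p = 0.18). The amino acid adenylation genes Npun_R3450 and Npun_R3433 had -3.28 ± 0.24 and -3.26 ± 0.22 (at least 5.19-fold and 4.54-fold lower), while Npun_R6587 and Npun_R5497, annotated alike, had 0.38 ± 0.24 and 0.27 ± 0.24. The chaperonins groL (Npun_R0829) and groES (Npun_R0830) had -2.78 ± 0.27 and -2.38 ± 0.22, in a list of 25 chaperones of which 5 rose and 5 fell (list adjusted p = 0.72). The iron-storage genes Bfr (Npun_F6212) and Dps (Npun_R3258) had -2.87 ± 0.26 (at least 5.21-fold lower) and -2.83 ± 0.22, in the oxidative stress list (list adjusted p = 0.25).

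Among genes that rose in darkness in the zwf strain, Npun_R1041 had 4.03 ± 0.26, Npun_F0517 had 3.69 ± 0.23, ycf46 (Npun_F0518) had 3.38 ± 0.23, PncB (Npun_F5709) and NadD (Npun_F5710), both of NAD synthesis, had 3.37 ± 0.23 and 2.83 ± 0.25 (at least 9.75-fold and 3.82-fold higher), and Npun_R1095, a possible phage baseplate protein, had 3.35 ± 0.22. Of the genes that fell in the zwf sigG strain, Npun_R0664 rose by 2.34, Npun_R4059 by 1.25 and sigG by 0.86 (adjusted p = 4.4e-07, 0.00036 and 0.01), at least 5.05-fold for Npun_R0664. The anti-sigma factor gene Npun_F4154 rose by 1.73 (adjusted p = 1.1e-05). The phage tail sheath genes Npun_F1402 and Npun_F1403, by contrast, fell, with -2.75 ± 0.26 (at least 3.72-fold lower) and -2.08 ± 0.22.

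Of the 27 lists, the ATP synthase list differed from other genes in this shift by camera, where 8 of 9 tested members fell, with a mean of -1.27 (adjusted p = 0.001), and 9 passed adjusted over the list alone. Its members included atpD (Npun_R4417) with -1.70 ± 0.26 and atpA (Npun_F4863) with -1.43 ± 0.22. The call was lost with an estimated correlation (adjusted p = 0.58). By fry, 11 of the 27 lists passed. That test asks whether a list's genes shifted at all, not whether they shifted more than other genes. With a scan day term the mean was -1.19 (adjusted p = 0.0022), and within scan day 1 it was -1.2 (adjusted p = 0.0032). Of 53 ribosomal protein genes, 13 fell and 4 rose, among them rplJ (Npun_F5853) with -2.48 ± 0.23 and the hibernation factor hpf (Npun_R2873) with 1.96 ± 0.22, and the list did not pass (adjusted p = 0.18). With a scan day term on the 4 replicate values, which leaves 1 residual degree of freedom, 1696 genes passed, and with that term on the 6 slides as separate values 1514. Within scan day 1 the number was 1290, and in the zwf sigG channel it was 676, of which 634 were also past the threshold in the zwf channel.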

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

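Of the tests in this part, those of scan day and dye bias, of a local artifact, turned dyes and the dark response for the nitrate genes, and of scan day for the neighbours of the phage tail sheath genes were chosen only after the result was seen. For the neighbour test, the bound written beforehand was reached only as a tie, and asking also for a p under 0.05 was decided after that. For the dark response across all tested genes, the name of the pattern was reworded after the result was seen, with the bound unchanged.

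The ribosomal protein genes had a mean difference of 0.204 between the conditions, past the threshold of camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.91) or without vegetative or akinete-induced replicate 2 (mean differences of 0.128 and 0.113, adjusted p = 0.24 and 0.75). Npun_F6209, a possible multicopper oxidase, was lower on all 3 vegetative slides and higher on all 3 akinete-induced slides, a difference of 1.17 that did not pass the adjusted test. Npun_F4149, upstream of sigG, had the opposite arrangement with a difference of -0.27, also short of the threshold. Among genes too dim to be tested, Npun_F5712, annotated as an NAD synthase, had a ratio of 3.10 on the slide of vegetative replicate 1, and Npun_F6157 (CbiM) had 2.09 on the slide of akinete-induced replicate 1.

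Nitrate assimilation genes were bright in the zwf sigG channel of akinete-induced replicate 1, with ratios of 4.22 for Npun_R1526 (nitrate reductase), 4.76 for Npun_R1527 (nitrate transporter) and 5.15 for Npun_R1528 (nitrite reductase), and dim in both channels of replicate 2. A local artifact is argued against by 6 spots in 6 print blocks whose duplicates differed by at most 1.26-fold, turned dyes by the sigG ratio of -4.46 there, and an exchange with a vegetative slide by a zwf channel that correlated more with both slides of akinete-induced replicate 2 than with any vegetative slide (difference of r at least 0.164). A culture that had simply stayed nearer the vegetative state is argued against for these genes, since they were brighter than in the zwf sigG channel of any vegetative slide by at least 4.68 (log2). Across all tested genes, the ratios of that slide, slide 4, correlated at r = -0.369 with the zwf shift measured without it. A weaker dark response of that culture would give such a negative r. For slides 5 and 6, r with the zwf shift measured from slide 4 was 0.0713 and -0.149. The test of an exchange used the zwf channel, so it covers the whole slide and not the zwf sigG extract alone. A slide of a culture outside the labels and a difference in medium or nitrogen supply of that flask stay open and were not tested, and so does a strain effect, since Npun_R1527 and Npun_R1528 were also above background in the zwf sigG channel alone in vegetative replicate 1 (1.32 and 1.44) but in neither channel of replicate 2 of either condition.

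Slides that shared a scan day had similar ratios even across conditions, with the lowest same-day r of 0.314 over 5 pairs and the highest different-day r of 0.188 over 4 pairs. That gap of 0.127 is consistent with a batch tied to the scan day, or to labelling and hybridisation steps that went with it. Gene-specific dye bias as the whole cause is argued against, because slides 2 and 5, with the same dye orientation, correlated less than slide 2 with slides 4 and 6 of the other orientation (difference of r -0.26). A strain effect shared by both conditions stays open as part of every pair, and no biological explanation of the gap itself was tested. Within a condition the days overlapped. Same-day pairs had r = 0.534 (slides 2 and 3) and 0.272 (slides 4 and 6). Different-day pairs had 0.348 (slides 1 and 2), 0.235 (slides 5 and 6), 0.0596 (slides 4 and 5) and 0.00652 (slides 1 and 3). Both slides of scan day 2, slides 1 and 5, had the same dye orientation, so day and orientation are partly tangled.

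The 9 tested genes from Npun_R1398 to Npun_F1407, of which 2 are annotated as phage tail sheath proteins, had negative mean ratios in vegetative growth. Single slides could lie near 0, as for Npun_R1398 with -0.08 on slide 3. A local artifact is argued against by the spots of the 9 genes lying in 16 print blocks. A scan day effect stays open: their mean was -0.644 or lower on each of the 3 vegetative slides, but several of them had been named for the same sign on all 3, so this decides nothing. With the cluster left out, 1 pair of neighbours was found among 21 genes of at least 2-fold ratio (permutation p = 0.17 over 10000 draws, one-sided), so whether neighbours in general differ together cannot be told apart from chance with so few genes. The strain difference that the design names stays open, and neither the genes' ratios nor their differences between conditions passed the adjusted limma test on the 4 values.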

How the results depend on the processing

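Most alternatives were fixed before the data were examined; those with a scan day term, within a scan day or with a crossed block, and the 2-fold counts without a replicate, were chosen after seeing the data. With 2 values per condition, fits left with 1 residual degree of freedom lean on the shared prior, so their counts swing widely. Where leaving out a replicate leaves a condition with 1 value, that value is assumed to vary like the other condition's, and many genes lie near background, which limits ratios of dim genes. The fit with scan day and dye terms treats all 6 slides as independent, since limma returned no correlation within replicates for it, and it thereby counts slides of the same extracts as separate values. The planned fit of the 6 slides with a dye term did not discount such slides either, since its estimated correlation within replicates was -0.119. The cause of the changes below was not tested, except that a stricter correction with the dim genes included and fewer residual degrees of freedom follow from how an alternative is built.

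In vegetative growth (2 genes), the number of genes past the threshold was 6 with no offset, 24 with median centring, 9 with print-tip loess, 0 with scaling between slides, 0 without the brightness filter, 17 with a dye term on 4 values, 41 and 12 on 6 slides with and without a dye term, 35 for the condition alone, 1 with the trended robust variance model, 0 with a scan day term and 0 within scan day 1, and leaving out a replicate or slide gave 0 to 35. After induction (3 genes) it was 6 without background subtraction, 83 with median centring, 5 with print-tip loess, 0 with scaling, 0 without the filter, 18 with a dye term on 4 values, 22 and 9 on 6 slides with and without a dye term, 0 for the condition alone, 22 with scan day and dye terms, 0 with a scan day term and 0 within scan day 1, and leaving out a replicate or slide gave 0 to 126. For the difference (0 genes) it was 3 with median centring and 2 with a dye term on 4 values, and leaving out a replicate or slide gave 0 to 64. With the replicate number as a block, 23, 56 and 2 genes passed for the vegetative, induced and difference tests, where the numbers mark no known pairing. The deviations of same-numbered replicates correlated at -0.307 between the conditions, and with the numbers crossed in the block 27, 29 and 2 genes passed. Of the list tests (5 past the threshold), 0 passed with an estimated correlation, 0 with fry, 10 with median centring and 8 with a dye term, and without a replicate 3 to 7. By the 2-fold rule, 32 vegetative genes became 64 within scan day 1 and 47 to 64 without a replicate, and 34 induced genes became 77 within scan day 2 and 37 to 175 without a replicate. Without replicate 2 or within scan day 2, 1 slide per condition was left, so any gene met the same-sign condition. The zwf shift (1245 genes) gave 676 in the zwf sigG channel, and without a replicate 840 to 1294.

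The sigG ratio ran from -6.02 with no offset to -4.08 in the authors' deposited table in vegetative growth and from -7.12 to -4.46 after induction, and its call held in 20 and 19 of 26 alternatives with a test. Npun_R4059 ran from -3.09 to -2.63 and from -3.82 to -2.44, held in 19 and 18, and Npun_R0664 after induction from -4.22 to -2.56, held in 19. Of 1460 alternatives for 55 results of named genes, 1186 kept direction and side of the threshold, 221 brought a gene past it, 35 lost a call, 5 moved by more than the replicate spread and 13 turned the sign, none of a gene past the threshold. Npun_F4025 (zwf) turned to 0.09 with print-tip loess and 0.10 in the authors' deposited table in vegetative growth, and after induction to 0.01 with median centring, 0.04 with print-tip loess, 0.10 without slide 6 (-0.28 to 0.10 over the replicates and slides left out) and 0.03 in the authors' deposited table. Npun_F4150 turned to -0.04 without vegetative replicate 2 (-0.04 to 0.66 over those left out), and after induction to -0.15 with a dye term on 4 values, -0.01 with a dye term on 6 slides, -0.02 without akinete-induced replicate 1, -0.10 without slide 6 (-0.10 to 0.22 over those left out), -0.05 with scan day and dye terms and -0.09 with a scan day term.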

Other observations

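The lists in this part were fixed beforehand, and the strain ratios in its last paragraph were picked after their values were seen. Genes of further lists passed singly in the zwf strain in darkness, while none of the lists counted here passed camera, and 1245 of all 2522 tested genes passed singly. Of 33 tested oxidative stress genes 12 fell and 6 rose, and of 39 two-component genes 18 rose and 4 fell (adjusted p of the lists = 0.25 and 0.18). Of 10 nitrogen assimilation genes 5 fell (list adjusted p = 0.18), among them gltB (Npun_R3877) with -1.52 ± 0.24 and amt (Npun_R3288) with -1.33 ± 0.23. Of 21 genes of NDH-1 and respiration 6 fell and 3 rose (list adjusted p = 0.21), with ctaD (Npun_F5533) of cytochrome oxidase at 1.53 ± 0.25. Of 33 genes of lipids and desaturases 14 rose and 7 fell (list adjusted p = 0.61). The fatty acid desaturases OLE1 (Npun_F3985) and DesA (Npun_R6231) fell, with -2.61 ± 0.23 and -2.16 ± 0.23 (for DesA at least 3.32-fold). Of 25 phycobilisome genes 3 rose and 2 fell (list adjusted p = 0.95), and nblA (Npun_F0291), of phycobilisome degradation, rose by 1.63 (at least 1.95-fold). In sugar metabolism 8 of 29 genes rose and 8 fell (list adjusted p = 0.98), with pyk (Npun_R0030) at 1.57 ± 0.22 (at least 1.4-fold higher) and eno (Npun_R3508) at -1.62 ± 0.23.

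The PRC-barrel genes Npun_F5451 and Npun_F5452, held in the akinete list, fell (-3.46 ± 0.24 and -2.37 ± 0.23) in the zwf strain in darkness. Of the other 2 members, the PRC-barrel gene Npun_R5740 rose (1.07 ± 0.23) and rimM (Npun_F1948) had -0.51 ± 0.22 and did not pass, nor did the list (adjusted p = 0.18). On the slide of akinete-induced replicate 1, Npun_F5452 had a strain ratio of 3.76, and the gene of unknown function Npun_R6615 had 3, against -0.17 and -0.13, and -0.14 and -0.32, on the slides of replicate 2.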
